A study of Mus musculus with 16 samples.

How the data were processed

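BMAL1 binding was measured by chromatin immunoprecipitation and sequencing in mouse liver, in 8 BMAL1 libraries and 8 IgG libraries of both sexes, control or misaligned treatment, and ZT0 or ZT12. Each group had 1 library, pooled from 3 to 4 mice. Per the submitters' processing notes, reads were aligned with BWA 0.7.17-r1188 to GRCm38 and peaks were called with MACS2 2.2.7.1. The q threshold, the effective genome size, the sequencing depth and whether the IgG libraries served as control are not stated. The misalignment schedule is not described in the labels.

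The deposited lists, 1 per BMAL1 library, give for each peak a score (10 times -log10 q, truncated, by the values), the fold enrichment of the summit over local background as a ratio, and -log10 p and -log10 q, all by the authors' peak caller. A deposited table merges overlapping peaks of the 8 lists into 7043 intervals, with a true or false call per library, the count of libraries and of merged peaks, the nearest gene and the distance to its TSS. The calls in it were checked against the lists, whose 9986 peaks were all accounted for. Fold enrichment and q depend on depth and background, so they were compared within a list, and set side by side between lists only to choose which genes to name. The authors' distance is to 1 transcript, and it can be far from the gene end in RefSeq, as at Per2 (-9470 bp) and Per3 (-13207 bp).

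The whole number of fragments at each summit and the local background were recovered from fold enrichment and -log10 p, which are both functions of the 2, with a relative tolerance of 0.0001. This succeeded for 99.1% to 100% of the peaks of each list. The lowest background in a list is proportional to the depth of the BMAL1 library times fragment length. A peak was called of high background when its local background was at least 5 times that value, and an interval when it held such a peak in at least 1 library. On simulated data, fragments were recovered for 100% of 1000 peaks, and 2.70% of 926 peaks with rescaled fragments were wrongly recovered. Planted overlaps of 60% of 300 peaks were found as 60%.

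Groups were taken from the labels. Peak numbers were compared within 4 strata for each of treatment, sex and time by an exact two-sided sign-flip permutation test on the log2 ratios, with Benjamini-Hochberg adjustment over the 3 tests. Sharing was the percentage of peaks of 1 list overlapped by at least 1 bp in the other, in both directions for 12 pairs, beside 100 random placements on the same chromosomes. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, as peaks are not replicates. Location used the authors' annotation.

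For 19 gene lists fixed before the data were examined, the members with a peak within 10 kb of the TSS, by the authors' nearest gene, were counted per library. The lists were core clock, clock output, cholesterol synthesis, lipogenesis, fatty acid oxidation, glucose metabolism and insulin signalling, bile acid and xenobiotic metabolism, male-biased and female-biased liver genes, abundant hepatocyte secretory genes, liver transcription factors, glucocorticoid response, heat shock, inflammation and acute phase, and markers of stellate, Kupffer and myeloid, endothelial, cholangiocyte and lymphocyte cells. Ppara and Por stand in more than 1 list. Each count was placed among 10000 random lists of the same size as a percentile, ties counted by their middle. The random lists were drawn from 21900 RefSeq protein-coding genes, in place of the genes the authors could assign, and were not matched for expression.

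The genes named were fixed by rule before the data were examined: every core clock gene, the genes nearest the 5 strongest peaks of each library by -log10 q, those nearest the 10 strongest intervals called in 1 library of a treatment pair and not the other, up to 4 members of each other list by highest -log10 q, and the 10 intervals called in all 8 libraries with the best mean rank. Some genes that this rule names are not analysed here. Alternatives planned before the data were examined were -log10 q of at least 3, chromosomes 1 to 19, X and Y, overlap of at least 50% of both peaks, lists of equal length, 5 kb in place of 1 kb for promoters, and 1 kb or any distance for gene lists. Added after seeing the data were leaving out peaks of high background, the chromosome filter for the sign-flip tests, and any RefSeq protein-coding gene within 10 kb. The last counted a peak inside the gene or within 10 kb of either end, and 1 peak could count for several genes. E-box and other motif shares and a repeat filter were not run, as they need the genome sequence. The IgG libraries were not used here.

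For the closing section, the strength of a site was the summit fragments minus local background, divided by the lowest background of the list, over the 26 intervals called in all 8 libraries with no peak of high background. The similarity difference of a library was its mean Pearson r of log2 strength across these sites with the ZT12 control libraries minus that with the ZT0 control libraries, a control library not being compared with itself, with a 95% interval from 10000 bootstrap draws of sites. The bound for excluding strength as a cause was at least 2 other libraries with an interval on the other side of 0 from the controls nearest to them. Nearest was by mean distance of median log2 strength. Sites are not independent replicates. In 200 simulated sets a profile of the other time was called by its interval in 94.5%, a profile of the wrong time in 0%, and with no difference the interval left out 0 in 8%. All simulated libraries had the same noise. In the data r was 0.850 between the ZT0 controls and 0.947 between the ZT12 controls, so these rates may not hold for them. Depth explanations were tested by dividing summit fragments and background by a depth ratio and counting the peaks still past the weakest p of the list. That p cut-off was held fixed at the value of the longer list, so the peaks left and the depth gaps needed may be overstated. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.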

Results

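BMAL1, the transcription factor that pairs with CLOCK to switch on genes of the circadian clock, was mapped in mouse liver by chromatin immunoprecipitation and sequencing. The 16 samples were 8 BMAL1 libraries and 8 IgG libraries, with 1 library of each kind for every combination of sex, treatment (control or misaligned) and time (ZT0 or ZT12 of a 12 h light and 12 h dark cycle). Each library held liver pooled from 3 to 4 mice aged 8 to 16 weeks on a diet with 42% of calories from fat. There were no replicates, so no difference between a pair of libraries could be set against replicate error. The values below are calls in the authors' peak lists of the BMAL1 libraries on GRCm38. The read depth of the libraries is unknown. The lowest local background in a list, which scales with depth and fragment length, was 6.16 fragments in male control ZT0, 4.32 in male misaligned ZT0, 4.39 in male control ZT12 and 4.25 in male misaligned ZT12. In females it was 4.84 fragments in control ZT0, 5.06 in misaligned ZT0, 5.67 in control ZT12 and 6.14 in misaligned ZT12, and the last 2 values rested on 4 peaks each.

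Genes of the core clock carried BMAL1 peaks in every library, in both sexes, under both treatments and at both times. Of the 22 genes of the core clock list, 10 had a peak within 10 kb of the annotated transcription start site (TSS) in all 8 libraries: the repressors Per1, Per2, Cry1 and Cry2, the nuclear receptors Nr1d1 and Nr1d2 (REV-ERB alpha and beta), Bhlhe40, Ciart, and the PAR-bZIP factors Dbp and Tef. Per3 and Hlf were the nearest gene to a peak in 8 of 8 libraries, with the Per3 interval at -13207 bp and Hlf within 10 kb in 5 libraries. Bhlhe41, a repressor related to Bhlhe40, had a peak within 10 kb in 6 libraries, all but the control ZT0 libraries of both sexes. Nfil3, the repressor that opposes the PAR-bZIP factors, had one in 3 libraries, which were male misaligned ZT0, male misaligned ZT12 and female misaligned ZT0. Rora was nearest to a peak in male misaligned ZT12 alone, and Arntl (the gene of BMAL1 itself), Clock, Npas2, Rorb, Csnk1d and Csnk1e had none by the authors' nearest gene.

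The number of core clock genes with a peak within 10 kb was 11 in male control ZT0, 13 in male misaligned ZT0, 11 in male control ZT12 and 13 in male misaligned ZT12. In females it was 10 in control ZT0, 13 in misaligned ZT0, 11 in control ZT12 and 12 in misaligned ZT12. Each count was at percentile 100 of 10000 random lists of 22 protein-coding genes, whose highest count was 9. Within 1 kb of the TSS the counts were 5 or 6 in the 7 libraries other than male misaligned ZT12. By RefSeq position, 3 libraries had a peak within 10 kb of Rora.

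**Figure D1:**
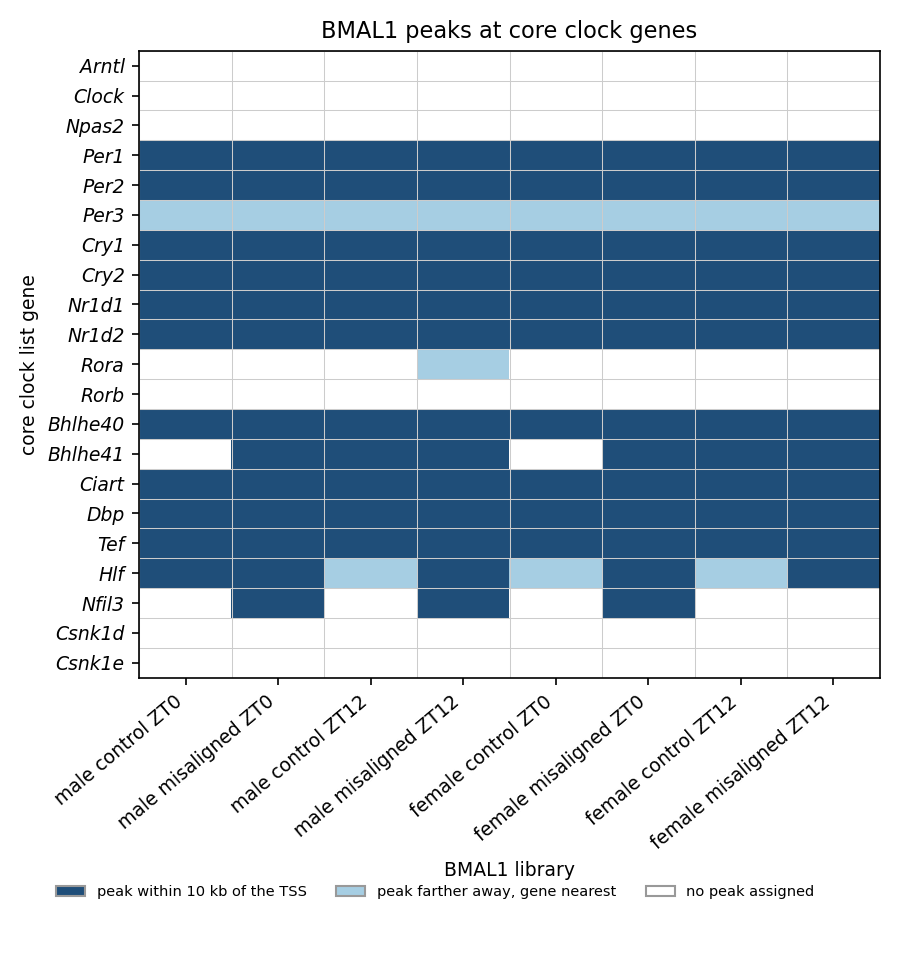
Calls at genes of the core clock list (vertical axis, 1 of the 22 genes not shown) in the 8 BMAL1 libraries (horizontal axis), with dark cells for a peak within 10 kb of the TSS and light cells for a peak farther away to which the gene was nearest. Per1, Per2, Cry1, Cry2, Nr1d1, Nr1d2, Bhlhe40, Ciart, Dbp and Tef are dark in all 8 libraries, and Nfil3 is dark in 3 misaligned libraries.

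Several of the strongest shared peaks were also at clock genes. Among the 34 intervals called in all 8 libraries, the interval with the best mean rank by -log10 q (2.88) lay on chromosome 9 from 44881170 to 44881971, within 10 kb of Kmt2a, a histone methyltransferase gene, although the authors' nearest gene was Gm26249 at -16295 bp. The interval at Nr1d2 (chromosome 14, 18238206 to 18239473, exon, 192 bp from the TSS) had a mean rank of 3 and ranked between 1 and 8 in the 8 lists. Next came Tef (chromosome 15, 81810161 to 81811833) at 5.88, Nr1d1 (chromosome 11, 98772547 to 98775932, intron) at 6.25 and Per1 (chromosome 11, 69094535 to 69095474) at 6.75. Per2 (chromosome 1, 91458796 to 91459875) followed at 8.50, the Nr1d1 interval from 98782941 to 98783909 at 9.12, Per3 (chromosome 4, 151044224 to 151045185) at 10, and the Dbp intervals on chromosome 7 at 11.2 and 12.8. At Per2 in female misaligned ZT12 the fold enrichment was 3.71 over a local background 10.5 times the lowest in that list, while the background at Per2 was 1.15 to 3.20 times the lowest in the other 7 libraries.

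Of the 5 strongest peaks of each library, those not in these intervals lay near the start of chromosome 9, where local background was high. Gm10718 (3024083 to 3024511) ranked 1 in female control ZT0 and 2 in both male control libraries, with a fold enrichment of only 1.65, 1.71 and 2.53. Gm10721, Gm11168 and Gm17535, in the same stretch, were also among the 5 strongest of male control ZT0 or female control ZT0. Peaks whose local background was at least 5 times the lowest of their list numbered 15 to 39 per library.

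Whether misalignment changed BMAL1 binding was addressed by 4 pairs of libraries of the same sex and time. More peaks were called in the misaligned library of all 4 pairs. In males there were 1864 peaks against 373 at ZT0 (ratio 5.00) and 5542 against 290 at ZT12 (ratio 19.1). In females there were 1330 against 225 at ZT0 (ratio 5.91) and 221 against 141 at ZT12 (ratio 1.57). The geometric mean ratio was 5.45 (mean log2 ratio 2.45, higher in 4 of 4 strata, exact two-sided sign-flip permutation test, p = 0.125, adjusted p = 0.188 over 3 comparisons). The smallest p that 4 strata allow is 0.125, so the test could not pass 0.05. At -log10 q of at least 3 the female control ZT0 list held 128 peaks and the ratio at female ZT0 was 8.80.

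**Figure D2:**
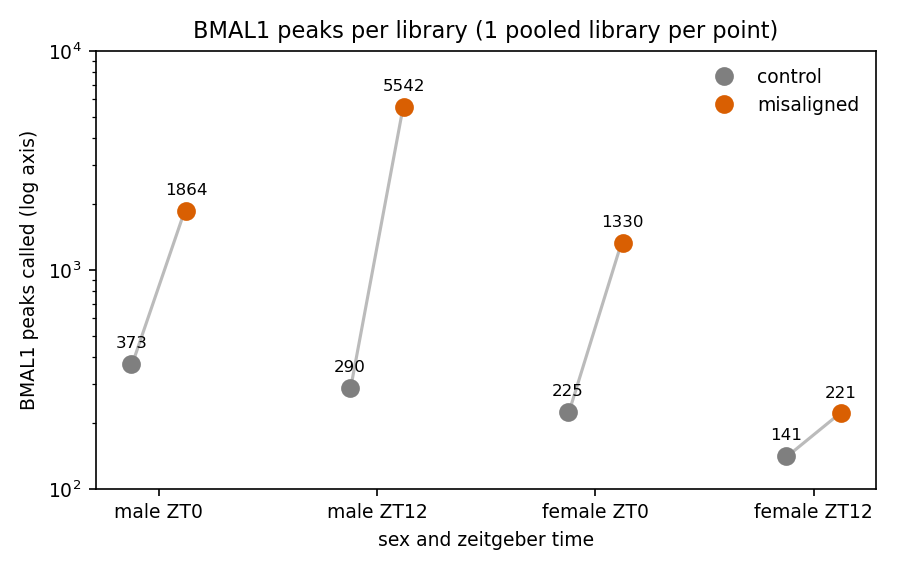
Number of called BMAL1 peaks (vertical axis, log scale) by sex and time (horizontal axis), with 1 point per library, lines joining the control and misaligned library of a pair, and no error bars because there were no replicates. The misaligned libraries held 1864, 5542, 1330 and 221 peaks, against 373, 290, 225 and 141 in the control libraries of the same sex and time.

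Most of the sites of control males were also called in misaligned males, and fewer of those of control females in misaligned females. The share of control peaks overlapped by a misaligned peak was 72.7% (exact Clopper-Pearson 95% interval 67.8 to 77.1, 271 of 373) in males at ZT0 and 78.3% (73.1 to 82.9, 227 of 290) at ZT12. It was 38.2% (31.8 to 44.9, 86 of 225) in females at ZT0 and 51.8% (43.2 to 60.3, 73 of 141) at ZT12. The reverse shares were 14.4%, 4.04%, 6.47% and 33.0%. Random placement gave at most 1.72%. With both lists shortened to the length of the shorter, the control shares were 52.5%, 48.6%, 24.9% and 47.5%, so the male and female values at ZT12 no longer differed beyond their counting error. When overlap of at least 50% of both peaks was asked, the ZT12 share was 45.2% in males and 48.2% in females, so the female share was then not the lower.

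**Figure D3:**
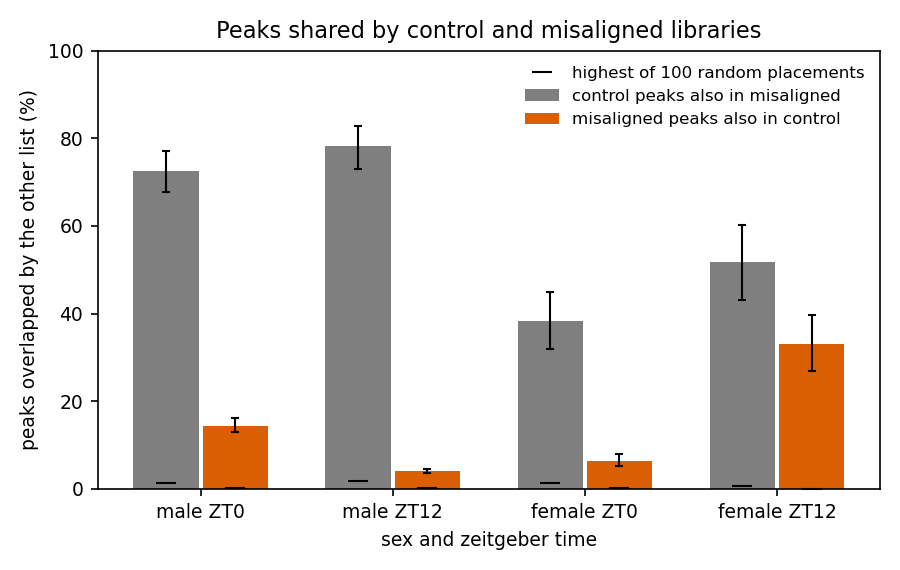
Share of the peaks of 1 list that overlap a peak of the other (vertical axis, percent) for the 4 control and misaligned pairs (horizontal axis), with exact Clopper-Pearson 95% intervals as error bars, grey bars for control peaks also in the misaligned list, orange bars for the reverse, and ticks for the highest of 100 random placements. The grey bars stand at 72.7% and 78.3% in males and at 38.2% and 51.8% in females.

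In males at ZT0, 1593 intervals were called in the misaligned and not the control library, 100 in the control and not the misaligned library, and 267 in both. Of the intervals called in the misaligned and not the control library, the strongest was at Bhlhe41 (chromosome 6, 145855627 to 145856385, -log10 q 57.8, fold enrichment 12.1). The others of the 10 strongest were nearest Gm22676, Tspan4, Hif1a (the oxygen-regulated transcription factor), 2610002J02Rik, Gm25301 (within 10 kb of Ppargc1b), Dgat2 (an enzyme of the last step of triglyceride synthesis), Fzd5, Gm21786 and Rapgef1, with -log10 q from 35.4 to 48.0. The 10 strongest called in the control and not the misaligned library were at Gm17535 and Gm10722 on chromosome 9, both of high background, and at Gm22721, Mgrn1, Gm14236, Ppp1r3c (a glycogen-targeting phosphatase subunit), Slc20a1, Gm23527, Gm13496 and Mnt, with -log10 q of 14.7 to 24.1 for these 8.

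In males at ZT12, 5317 intervals were called in the misaligned and not the control library, 63 the other way and 223 in both. The 10 strongest on the misaligned side were nearest Gm15765, Gm15904, Cyth1, Snx9, Ddx50, Ndufa6 (a subunit of respiratory complex I), Slc30a1 (a zinc exporter), Mepce, Gm12902 and Phf1, with -log10 q from 81.6 to 102. The Cyth1 interval, on chromosome 11 from 118248203 to 118249490, was called in 6 libraries. Of the 10 strongest on the control side, 8 were intervals of high background, at Gm10722, Gm10719, Gm11168, Gm10717, Gm17535 and Gm22862 and on the Y chromosome at Gm29277 and Gm28389. The other 2 were at Pcca, a subunit of propionyl-CoA carboxylase, and Gm37352, with -log10 q of 15.3 and 13.9. The Gm29277 interval was of high background in other libraries only. Its peak in male control ZT12 (261061 to 261452, fold enrichment 11.5, local background 9.12 fragments) was not.

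In females at ZT0, 1237 intervals were called in the misaligned and not the control library, 137 the other way and 86 in both. The strongest on the misaligned side lay 100972 bp from its nearest gene, Gm26501 (-log10 q 99.3). It was followed by the interval at the Cry2 promoter (chromosome 2, 92433801 to 92434592, -log10 q 80.9), and then by Zfp292, Klf15 (a glucocorticoid-induced regulator of amino acid and glucose metabolism), Nptn, Hmgn2, the mitochondrial mt-Tp (of high background), 1810013L24Rik, Klf11 and Usp2 (a ubiquitin protease), with -log10 q from 51.4 to 65.9. The 10 of the control library were at Gm17535, Gm10719, Gm10722 and Gm11400, all of high background, and at Ola1, Yif1b, Hacd1, Neu2, Slc38a9 and 4732463B04Rik, with -log10 q of 5.68 to 8.94 for these 6.

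In females at ZT12, 147 intervals were called in the misaligned and not the control library, 68 the other way and 70 in both. The 10 strongest on the misaligned side were at Gm22676, Gm10722 and mt-Th (both of high background), Gnpnat1, Klf11, Kdm6b (a histone H3K27 demethylase), Hmgn2, AC158786.1, Hnf4aos (within 10 kb of the hepatocyte regulator Hnf4a) and Usp2, with -log10 q from 24.4 to 73.0. Klf11 and Hmgn2 were named at ZT0 as well, by the same intervals. Usp2 was named at both times by different intervals (44084463 to 44085118 at ZT0 and 44085520 to 44086609 at ZT12). The 10 of the control library were at Lsm3, Gpt (alanine aminotransferase), RP24-142B15.11, Gm15653, Gm12902, Sertad1, Slc30a1, Inmt, Gm8532 and Atad1, with -log10 q from 13.4 to 34.5. The same Slc30a1 and Gm12902 intervals were on the misaligned side in males at ZT12.

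Among clock output genes, known targets of the clock in liver, more members had a peak in misaligned libraries, as did more genes overall. Of the 12 genes of this list, 4 had a peak within 10 kb in male control ZT0 and 7 in male misaligned ZT0, and 3 in male control ZT12 and 8 in male misaligned ZT12. No member had one in either female control library, against 7 in female misaligned ZT0 and 5 in female misaligned ZT12. RefSeq genes within 10 kb of a peak were also counted, a wider rule that takes in the whole gene. In the same order these counts were 5, 8, 6 and 10 in males. In females they were 0 in control ZT0, 8 in misaligned ZT0, 1 in control ZT12 and 6 in misaligned ZT12. Over all protein-coding genes, those with a peak within 10 kb of the TSS numbered 184 in male control ZT0 and 802 in male misaligned ZT0, 106 and 2046 at ZT12, and in females 94 and 673 at ZT0 and 54 and 100 at ZT12. Usp2 was called in 6 libraries (-log10 q 96.0 in male misaligned ZT12), Por (the electron donor of cytochrome P450 enzymes) in 5 (51.1), and Nampt (the rate-limiting enzyme of NAD salvage) and Wee1 (a kinase that restrains mitosis) in 4 each (41.3 and 39.8). The 4 libraries with Nampt were the 4 misaligned ones. Each of the 6 counts above 0 was at percentile 100 of the random lists, and differences between counts were not tested.

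Metabolic lists carried their highest counts in male misaligned ZT12, the longest list. There, 8 of 20 cholesterol synthesis genes (percentile 99.995 of random lists), 9 of 18 genes of glucose metabolism and insulin signalling (99.995), 5 of 18 lipogenesis genes (98.7), 4 of 22 fatty acid oxidation genes (90.0) and 4 of 19 genes of bile acid and xenobiotic metabolism (94.2) had a peak within 10 kb. In the same order the counts were 4, 5, 3, 2 and 3 within 1 kb of the TSS, and 14, 14, 13, 12 and 8 for RefSeq genes within 10 kb of a peak. The RefSeq rule takes in the whole gene and allows several genes per peak. Its counts are therefore not on the same footing as the TSS counts, and are given without their place among random lists. Among the strongest there were Insig1 (-log10 q 44.8) and Sc5d (14.3) for cholesterol, and Thrsp (85.9, of high background), Dgat2 (61.6) and Elovl6 (15.3) for lipogenesis. For glucose metabolism they were Slc2a2 (the hepatocyte glucose transporter, 40.1), Irs2 (25.8), Pcx (16.9) and Ppargc1a (11.2), and for fatty acid oxidation Ppara (33.6), Acadm (11.3), Cpt1a (7.34) and Fgf21 (4.70). Bile acid genes were led by Por, Cyp8b1 (5.28) and Cyp7a1 (the rate-limiting enzyme of bile acid synthesis, 2.64). Srebf1 was called in female misaligned ZT0 alone (18.5), and Nr0b2 in 4 libraries. In the other 7 libraries the counts of these 5 lists were between 0 and 3. Percentiles were not highest in male misaligned ZT12 for every list. In male control ZT12 they were 99.8 for lipogenesis (2 genes), 99.8 for bile acid and xenobiotic metabolism (2) and 94.7 for fatty acid oxidation (1). There glucose metabolism was at 99.8 (2) and cholesterol synthesis at 45.4 (0).

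Lists of hepatocyte identity and of stress carried their highest counts in the same library. In male misaligned ZT12 a peak lay within 10 kb of 7 of 22 abundant hepatocyte secretory genes (percentile 99.8, led by Cps1, Rbp4 and Apoe), 5 of 11 liver transcription factors (99.9, Foxa3, Foxa2, Onecut1 and Nr2f2 strongest) and 8 of 20 inflammation and acute phase genes (99.995, led by Socs3, Orm2, Cxcl1 and Il6ra). It held 3 of 10 glucocorticoid response genes (96.3, Klf9, Dusp1 and Nr3c1) and 3 of 10 heat shock genes (96.3, Hsph1, Hspd1 and Hspa8). Male-biased liver genes had 4 of 15 members (97.4, Cyp2u1, Gstp1, Mup20 and Bcl6) and female-biased liver genes 4 of 18 (95.2, led by Cyp17a1, Cyp2a4 and Cyp2b9). In the order given, the counts of these 7 lists were 3, 0, 4, 3, 3, 0 and 0 within 1 kb of the TSS. By the wider rule of RefSeq genes within 10 kb of a peak they were 10, 7, 11, 5, 4, 6 and 6. Their counts within 10 kb of the TSS were 0 to 3 in the other 7 libraries. In female misaligned ZT0 the glucocorticoid response and heat shock lists, with 2 members each, were at percentile 98.0. The other lists of this group stood lower there than in male misaligned ZT12. Ahsg was called in both misaligned male libraries, and Trim24 in female misaligned ZT0 alone. Markers of stellate cells, Kupffer and myeloid cells, endothelium, cholangiocytes and lymphocytes had 0 members with a peak within 10 kb in all 8 libraries. Random lists of the same sizes held 0.0196 to 1.12 members on average, and a count of 0 was at percentile 15.3 to 49.0. These lists were thus too short for a count of 0 to set them apart from random lists. At any distance from the nearest gene, 3 of 12 endothelial markers had a peak in male misaligned ZT12. When RefSeq genes within 10 kb of a peak were counted, all but the lymphocyte markers had 1 or 2 members in at least 1 misaligned library. The random lists were not matched for expression or open chromatin.

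Whether BMAL1 binding differed between the sexes was addressed by 4 pairs of the same treatment and time. Fewer peaks were called in the female library of all 4 pairs. The female to male ratio was 0.603 in controls at ZT0, 0.486 in controls at ZT12, 0.714 in misaligned mice at ZT0 and 0.0399 in misaligned mice at ZT12, and in controls at ZT0 it was 0.361 at -log10 q of at least 3. Core clock genes had 10 to 13 members called in each library of either sex. Clock output genes were called in control males (Ppara and Usp2 at both times, Klf10 and Wee1 at ZT0, Por at ZT12) and in no control female library. By RefSeq position, however, a member had a peak in female control ZT12. Control females also had fewer protein-coding genes with a peak, 94 against 184 at ZT0 and 54 against 106 at ZT12. Median female to male strength ratios at the 26 common sites were 0.714 and 0.654 in controls and 0.767 and 0.372 in misaligned mice (ZT0 and ZT12). A sex difference at clock output genes was not tested. Of the female peaks, 32.4% (26.4 to 39.0) were shared with males in controls at ZT0, 60.3% (51.7 to 68.4) in controls at ZT12, 41.5% (38.8 to 44.2) in misaligned mice at ZT0 and 80.5% (74.7 to 85.5) in misaligned mice at ZT12. The last share was 43.9% at equal list length and 50.2% with overlap of at least 50% of both peaks, and the control ZT0 share was 50% at -log10 q of at least 3. The geometric mean ratio was 0.302 (mean log2 ratio -1.73, higher in 0 of 4 strata, exact two-sided sign-flip permutation test, p = 0.125, adjusted p = 0.188), again the smallest p possible.

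Whether binding differed between ZT0 and ZT12 was addressed by 4 pairs of the same sex and treatment. The ZT12 to ZT0 ratio of peak counts was 0.777 in control males, 0.627 in control females, 2.97 in misaligned males and 0.166 in misaligned females. In controls of both sexes Bhlhe41 was called at ZT12 and not at ZT0. In control males Por, Dgat2, Pck1 (the gluconeogenic enzyme), Nr0b2 and Rbp4 were called at ZT12 and not ZT0, and Wee1, Klf10 and Insig1 at ZT0 and not ZT12. In misaligned females Nfil3, Wee1, Klf10, Dgat2, Pck1 and Slc2a2 were called at ZT0 and not ZT12. Mvd was called at ZT12 and not ZT0 in misaligned females. These members of the lists were picked out after their calls were seen. Over all intervals, 236 were called at ZT0 and not ZT12 in control males, 155 the other way and 131 in both. The same counts were 181, 96 and 42 in control females, and 1175, 69 and 148 in misaligned females. The ZT0 peaks shared with ZT12 were 36.5% (31.6 to 41.6) in control males, 53.0% (50.7 to 55.2) in misaligned males, 19.1% (14.2 to 24.9) in control females and 11.3% (9.63 to 13.1) in misaligned females. At equal list length the share in misaligned females was 47.1%, and in control females 30.5%. At -log10 q of at least 3 the control female share was 32.0% and their ratio of counts 0.977. The mean log2 ratio of counts was -0.51 (higher in 1 of 4 strata, exact two-sided sign-flip permutation test, p = 0.625, adjusted p = 0.625).

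The share of BMAL1 intervals within 1 kb of a TSS was 43.6% (38.5 to 48.8) in male control ZT0, 34.3% (32.1 to 36.5) in male misaligned ZT0, 31.5% (26.1 to 37.2) in male control ZT12 and 28.0% (26.9 to 29.2) in male misaligned ZT12. In females it was 36.8% (30.4 to 43.5) in control ZT0, 45.6% (42.9 to 48.3) in misaligned ZT0, 39.1% (30.9 to 47.8) in control ZT12 and 40.6% (34.0 to 47.4) in misaligned ZT12. Introns held 33.5% of intervals and intergenic sequence 24.9% in male misaligned ZT12, against 18.5% and 13.1% in male control ZT0. Within 5 kb the shares were 43.6% to 65.9%.

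The sex chromosomes held few peaks. On the Y chromosome 2, 2, 8 and 1 peaks were called in the male libraries (control ZT0, misaligned ZT0, control ZT12 and misaligned ZT12), nearly all at Gm29277. Among the female libraries, control ZT0 had 1 Y peak, at Gm21742 (90811301 to 90811577) and of high background, and the others had 0. On the X chromosome 0, 2, 1 and 34 peaks were called in males in the same order and 3, 4, 0 and 1 in females (control ZT0, misaligned ZT0, control ZT12 and misaligned ZT12). The 34 X peaks of male misaligned ZT12 were 0.613% (0.425 to 0.856) of its list, while 4.41% of protein-coding genes lie on X. The 3 X peaks of female control ZT0 were 1.33% (0.276 to 3.85) of its list. X copy number was not allowed for in setting these shares beside the gene share.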

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

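The tests of depth and of enrichment in this part were chosen only after the result was seen, while the test of local background was set before its value was known.

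From ZT0 to ZT12 the number of BMAL1 peaks went up in misaligned males (ratio 2.97) and down in misaligned females (0.166), and it went down in control males (0.777). Nfil3, Wee1, Klf10 and Dgat2 were called at ZT0 and not ZT12 in misaligned females, and at both times in misaligned males. They were picked out after their calls were seen, and Mvd went the other way in misaligned females. Of all intervals there, 1175 were called at ZT0 and not ZT12, 69 the other way and 148 in both. These calls therefore single out no gene. Each ratio compares 1 library with 1 library, so the difference between sexes, and that between misaligned and control males, was not tested.

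The tables argue against depth as the cause, if fragment length was alike. The lowest background was nearly the same at both times in misaligned males (ZT12 to ZT0 ratio 0.984). In misaligned females it went the other way from the counts (1.21). The female ZT12 value rests on 4 peaks. In females a 6.77-fold gap in favour of ZT0 would be needed, which the fixed p cut-off may overstate. At the 26 common sites, local background relative to the lowest of the list was 1.24 times as high at ZT12 as at ZT0 in misaligned females. With its backgrounds raised by that ratio, the ZT0 list kept 1185 peaks, 5.36 times the 221 of the ZT12 list. A rise of that size was thus too small. The common sites were all called and not of high background, so a larger rise at sites not called at ZT12 was not excluded. Enrichment at the 26 common sites moved with the counts in misaligned mice (median ZT12 to ZT0 strength ratio 1.67 in males and 0.788 in females). A change in immunoprecipitation yield and one in BMAL1 on the DNA cannot be told apart with 1 library per group, and in controls strength was higher at ZT12 (2.11 in males and 1.84 in females) while counts were lower (0.777 and 0.627). A sex difference in the response to misalignment stays open, as untested.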

How the results depend on the processing

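The alternatives without high-background peaks, the chromosome filter for the sign-flip tests and the RefSeq gene within 10 kb were chosen after seeing the data, and the others were planned. The 3 sign-flip results kept their direction and side of the threshold under all 3 alternatives run for each, which says nothing of stability as p could not go below 0.125. Peak counts stayed within 1.5 times in 23 of 24 cases, the exception being female control ZT0 with 128 peaks at -log10 q of at least 3. Of the sharing values, 27 of 48 stayed within their counting interval and 26 of 48 in the opposite direction. With overlap of at least 50% of both peaks, control peaks found in misaligned lists were 62.5% (male ZT0), 45.2% (male ZT12) and 28.4% (female ZT0), female peaks in males 36.4% (misaligned ZT0) and 50.2% (misaligned ZT12), and ZT0 peaks at ZT12 42.3% (misaligned males). With lists of equal length, control peaks in misaligned lists were 52.5%, 48.6% and 24.9% in the same order, female peaks in males 38.7% (misaligned ZT0) and 43.9% (misaligned ZT12), and ZT0 peaks at ZT12 42.1% (control males), 39.2% (misaligned males), 30.5% (control females) and 47.1% (misaligned females). At -log10 q of at least 3, female control ZT0 peaks were 56.2% in female misaligned ZT0, 50% in male control ZT0 and 32.0% in female control ZT12, misaligned ZT0 peaks of females were 44.7% in males, and those of males 60.9% at ZT12. Without high-background peaks, 83.3% of male control ZT12 peaks were in male misaligned ZT12. Within 5 kb of a TSS lay 65.9%, 50.6%, 51.4% and 43.6% of male intervals (control ZT0, misaligned ZT0, control ZT12, misaligned ZT12) and 55.6%, 59.9%, 58.0% and 60.8% of female ones, a wider window by construction. At -log10 q of at least 3 the share within 1 kb was 37.8% in male misaligned ZT0, 30.5% in male misaligned ZT12 and 43.7% in female control ZT0. Core clock genes within 1 kb numbered 5 in male control ZT0, male misaligned ZT0, male control ZT12, female control ZT0, female control ZT12 and female misaligned ZT12, and 6 in female misaligned ZT0, the other 33 of 40 values staying within 1.5 times. The other 18 lists stayed within 1.5 times in 618 of 720 values, with 70 higher and 32 lower. A narrower window or stricter overlap can only lower a value, and for the rest the cause was not tested. No paired analysis was possible by replicate number because every library carries the same number, 1, and the sign-flip tests matched libraries by stratum instead. E-box shares with their 2 alternatives and the repeat filter were not run. The unknown depth limits what an uncalled site means, and the absence of a call was not read as absence of binding.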

Other observations

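The tests of depth in males, of enrichment, of strength and of a swap in this part were chosen only after the result was seen. The bound for excluding strength was set again 2 times after its value was known, so it cannot decide. The tests of depth in females and of core clock sites alone were set before their values were known.

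A small set of sites was called in all 4 misaligned libraries and in no control library, and was picked out after its calls were seen. It included 15 intervals, with no number expected by chance computed, and the misaligned list was the longer in every pair. Among them were intervals at Nampt (chromosome 12, 32819706 to 32820491, fold enrichment 4.39 to 7.28), Nfe2l2 (the regulator of the antioxidant response), Lss (lanosterol synthase, of cholesterol synthesis), Macrod1, Lhpp, Ntpcr, Rer1, Rbbp6, Syncrip, Thap4, Zbtb14, Sox5os1, Gm25794 and 2610002J02Rik. A further 200 intervals were called in the 3 misaligned libraries other than female ZT12 and in no control. Of all 7043 intervals, 5328 were called in misaligned males only, 426 in misaligned females only, and 4106 in male misaligned ZT12 alone.

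More peaks were called in misaligned than in control libraries in all 4 pairs. If fragment length was alike, the tables argue against deeper sequencing in males, where the lowest background was no higher in misaligned libraries (highest ratio 0.969). They also argue against it in females, where the ratio was only 1.04 at ZT0 and 1.08 at ZT12. Rescaling by so little left 5.87 times the control's peaks at ZT0 and 1.55 times at ZT12. The ZT12 ratio rests on 4 peaks per list. A 2.73-fold depth gap would be needed there, which the fixed p cut-off may overstate. Strength at the 26 common sites, among them Nr1d2, Tef and Per1, had median misaligned to control ratios of 2.29 and 2.05 in males and 2.89 and 1.23 in females (ZT0 and ZT12), with 25, 26, 26 and 21 sites higher, so stronger enrichment at most sites may underlie the counts. Yield of the immunoprecipitation and more BMAL1 on the DNA cannot be told apart with 1 library per group, and in controls strength and count moved in opposite directions between times.

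Relative strengths of the 26 common sites in male misaligned ZT0 resembled the ZT12 controls (mean r 0.927 across sites) more than the ZT0 controls (0.783), a difference of 0.144 (bootstrap 0.0414 to 0.272), a pattern noticed while comparing several sets of sites. The ZT0 controls themselves gave -0.0998 (-0.283 to 0.0303) in males and -0.0684 (-0.212 to 0.0507) in females, and both intervals included 0. The ZT0 controls were also less alike (r 0.850) than the ZT12 controls (0.947). If they are noisier, the measure leans to the ZT12 side. Strength of enrichment as the cause was not settled. Over the 26 sites, 2 libraries did not resemble the controls nearest to them in median strength. Female misaligned ZT0 (22.7, against 22.8 in male control ZT12) gave -0.164 (-0.332 to -0.0432). Its interval was -0.294 to -0.0350 without background subtraction and -0.954 to -0.0743 without core clock genes. Over 30 sites called in 6 libraries its interval was -0.245 to 0.0219, so it no longer counted against strength. Female control ZT12 (12.4, against 11.6 in male control ZT0) gave 0.174 (0.0679 to 0.332, and 0.0812 to 0.294 over the 30 sites). That library is itself 1 of the ZT12 controls. The tables argue against sites at core clock genes alone (0.269 without them, 0.0276 to 0.748, 13 sites). A swap of the male misaligned libraries would need ZT12 to resemble the ZT0 controls, if misaligned males kept the control timing. The male misaligned ZT12 library gave 0.164 (0.0603 to 0.283, and -0.0402 to 0.658 without core clock genes). This cannot decide on a swap, as the timing in misaligned males is itself open and the measure may lean to the ZT12 side. Strength of enrichment and a swap stay open. So do a shift in the timing of BMAL1 binding in misaligned males, a single wrong time label and an unlabelled batch, none of which was tested.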
